A study of Drosophila melanogaster x Drosophila sechellia and Drosophila melanogaster and Drosophila sechellia with 12 samples.

How the data were processed

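Heads of adult female flies were profiled by mmPCR-seq in 12 libraries. Groups and replicate numbers were taken from the sample titles: D. melanogaster (n = 2), D. sechellia (n = 2), mixed parents (n = 2), F1 hybrids (n = 3) and F1 hybrids with a mutant D. melanogaster Adar gene (n = 3). The labels do not say that replicates came from separate cultures or sets of animals, so p-values measure the spread between these libraries, which may be technical. Replicate pairs were compared before averaging; no pair was identical, and coverage differed by more than sampling noise in every pair (chi-square per degree of freedom 1.85 to 4.16).

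The authors deposited, per the file headers, 1 table per library with counts of A and G reads at each site for the D. melanogaster and the D. sechellia sequence, and an editing percent for each species. These deposited counts are whole numbers without normalization. The deposited percent equals the share of G reads, rounded, and is listed as 0 where a site has no read, so it was not used and levels were computed from the counts. Reads were aligned with BWA and positions refer to dm3, per the submitters' processing notes; the version of BWA, the rule that assigned reads to a species and the filters behind the list of sites are not given in the sources used here. PCR reads here carry no molecular identifiers in the tables, so read counts are not independent molecules, and intervals and limits from counts cover counting error only. Read assignment can move reads between alleles where the species sequences are alike, which would draw allele levels together in samples that hold both species.

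The tables list 1058 sites; 1 D. sechellia library lacks 1 of them, which was taken as having no reads. Total reads per library ranged from 251870 to 398284. Levels in the parent libraries used reads of their own species, and the other libraries used reads of both alleles, or of each allele in allele comparisons. A site entered a comparison with at least 50 reads in every library, or every allele of every library, that was compared, and a mean level of at least 1%.

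Each site was tested with a quasi-binomial logistic regression on G and A reads. Pearson dispersions were squeezed across sites with limma's squeezeVar on a trend with coverage and set to at least 1, effects were tested with a deviance F test, and p-values were adjusted by Benjamini-Hochberg over sites with a threshold of 0.05. Dispersion came from all 5 groups for comparisons of libraries. Allele comparisons within F1, within the mixed parents and between Adar F1 and F1 kept the library as a block. The change of gap between parents and F1 was tested without a library block. Both allele counts of a library were thus treated as independent there. The change of gap was tested as an interaction on the log-odds scale, so a gap that changes in percentage points near 0 or 100% need not pass. Adjusted p-values in the report come from this test. Mean levels per library were compared by exact two-sided permutation tests. Sites within 1000 bases of the next were joined into 309 clusters, and 95% intervals of medians, slopes and correlations came from 2000 resamples of clusters. Permutation tests used 100000 permutations.

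The named sites are the 10 largest rises and 10 largest falls per comparison among sites past the threshold whose libraries do not overlap between groups, at most 2 per cluster. The rule fixed before the data were examined allowed 2 per gene; clusters took the place of genes because the tables carry positions without gene names. For the same reason the gene lists and site classes fixed beforehand were not used here. Sites named outside this rule are said to have been chosen after their values were seen.

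The test was tried on simulated beta-binomial counts with the real coverage and dispersion. For the species comparison it recovered 26.9%, 73.1% and 89.4% of sites changed by 0.5, 1 and 2 in log odds, over 762 sites, and 0.787% of its calls were false. For Adar F1 against F1 it recovered 38.8%, 85.1% and 90.9% over 648 sites, with 3.38% of calls false, and for F1 against mixed parents 44.8%, 62.7% and 93.9% over 853 sites. For alleles in F1 it recovered 52.9%, 57.6% and 84.8% over 512 sites, and for alleles in mixed parents 14.7%, 51.5% and 54.5% over 521 sites. For the change of gap between parents and F1 it recovered 8.82%, 48.5% and 81.8% over 499 sites, with 8% of calls false. For the change of gap in Adar F1 it recovered 11.8%, 48.5% and 72.7% over 324 sites, with 4.35% of calls false.

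Alternatives fixed before the data were examined were coverage minimums of 20 and 100 reads, level minimums of none and 5%, limma on arcsine-square-root levels, Fisher's exact test on pooled counts, a minimum difference of 5 percentage points, only the compared groups in the fit, a replicate block, thinning to equal coverage, mixed parents as the species difference, leaving out each replicate, and, for mean levels, the median over sites and pooled reads. Leaving out sites at 95% G, single-allele reads, sites whose allele share moved by over 30 percentage points, reads of both species in the parents and the coverage batch were added after seeing the data. Analyses used R 4.3.3 with limma 3.58.1, and figures used Python 3.11.15 with matplotlib 3.10.9.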

Results

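RNA editing was measured in heads of adult female flies, 0 to 2 days old, by microfluidic multiplex PCR and sequencing (mmPCR-seq), in which many known editing loci are amplified from cDNA together and sequenced. Adar, the enzyme that converts adenosine to inosine in double-stranded RNA, makes an edited position read as G where the gene has A, so that the editing level of a site is the percentage of G among its A and G reads. The 12 libraries formed 5 groups: Drosophila melanogaster (n = 2), its relative Drosophila sechellia (n = 2), a mixture of both parent species prepared as a control (n = 2), their F1 hybrids (n = 3), and F1 hybrids carrying a mutant D. melanogaster Adar gene, called Adar F1 here (n = 3). Each read had been assigned to the D. melanogaster or the D. sechellia sequence, which gave the A and G counts of both alleles at 1058 sites of the dm3 build. Of these, 161 lay on chromosome arm 2L, 256 on 2R, 148 on 3L, 260 on 3R, 14 on chromosome 4 and 219 on X. Sites are named by dm3 position because the tables pair them with no gene.

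The libraries held between 251870 reads (mixed parents replicate 1) and 398284 reads (Adar F1 replicate 2), with a median of 220.5 to 309 reads per site. At 682 sites every library had at least 50 reads. The D. melanogaster sequence took 63.2% and 62.9% of the reads of the mixed parents, 65.5%, 65.8% and 65.4% of those of the F1 libraries, and 60.8%, 59.6% and 59.7% of those of the Adar F1 libraries. The Adar F1 libraries lacked reads at 188 to 196 sites each, against 6 to 32 sites in the other libraries.

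Mean editing over the 682 shared sites was 18.3% ± 0.0485 (SD, n = 2) in D. melanogaster and 15.8% ± 0.836 (n = 2) in D. sechellia. It was 17.1% ± 0.569 (n = 2) in the mixed parents and 17.3% ± 0.480 (n = 3) in F1, and it was 15.4% ± 0.902 (n = 3) in Adar F1. The 3 Adar F1 libraries all lay below the 3 F1 libraries, at 16.4%, 14.7% and 15.0% against 17.8%, 16.9% and 17.2%. For this comparison the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow, and 0.333 after Benjamini-Hochberg adjustment over the 10 pairs of groups. The species difference had an exact permutation p = 0.333, which is the smallest that 2 against 2 libraries allow, and the adjusted value was 0.417. F1 and mixed parents differed by 0.160 percentage points, less than the spread between their replicates (exact permutation p = 0.8).

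**Figure D1:**
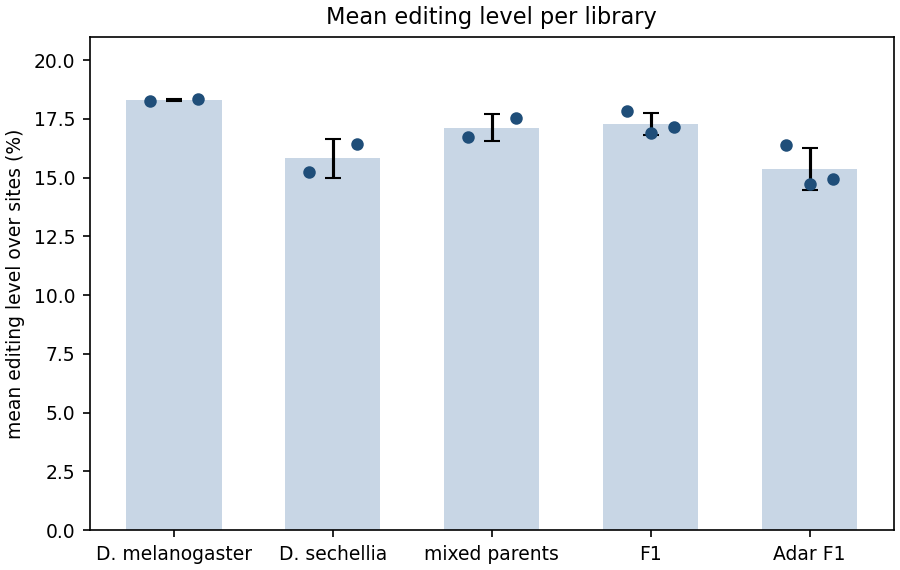
Mean editing level (%) of each library over the 682 sites with at least 50 reads in all 12 libraries. Points are libraries, bars group means and error bars ± 1 SD (n = 2, 2, 2, 3 and 3); D. melanogaster had the highest mean at 18.3% and Adar F1 the lowest at 15.4%.

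The parent species were compared to find sites edited to different levels. Of 762 sites tested, 319 in 143 clusters of neighbouring sites differed, of which 122 were higher and 197 lower in D. sechellia, with a median absolute difference of 10.4 percentage points among them. The largest differences were nearly complete switches. On 3R at 5296946 the G percentage was 99.4% ± 0.238 (SD, n = 2) in D. sechellia and 0.314% ± 0.445 (n = 2) in D. melanogaster (adjusted p = 9.31e-15). On X at 4253674 it was 99.3% ± 0.337 and 0.588% ± 0.264, and on 2L at 17371335 it was 97.8% ± 0.605 and 2.26% ± 1.16. In the opposite direction, 3R 4067707 stood at 0.209% ± 0.296 in D. sechellia and 98.5% ± 0.118 in D. melanogaster. At 2R 13262655, no D. sechellia read was G, which allows a level of up to 1.06%, and the D. melanogaster level was 98.4% ± 0.261.

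All 10 named sites of each direction read as G in at least 95% of the reads of at least 1 species, as did 39 of the 891 sites covered in both species. Without the genomic sequence of each stock, an edited adenosine and a genomic G give the same reads there. Of these 39 sites, 12 had at most 5% in D. sechellia with at least 95% in D. melanogaster, 6 had the opposite arrangement, and 10 were at 95% or more in both. With these sites left out, 293 of 723 sites differed. Among those sites, chosen after their values were seen, X 1267594 was edited at 79.8% ± 1.36 in D. sechellia and 19.9% ± 1.61 in D. melanogaster, and X 3847311 at 51.9% ± 2.12 and 6.997% ± 0.628. The site 2R 17508581 was at 48.0% ± 4.31 and 8.93% ± 0.359. Higher in D. melanogaster were 3R 16846284 (70.8% ± 0.819 against 3.02% ± 2.01), X 1272317 (50.7% ± 3.85 against 7.38% ± 2.18) and 3R 1062097 (45.9% ± 1.196 against 0.506% ± 0.452). Sites on X differed more than those elsewhere: 59.0% of 144 sites on X and 37.9% of 618 others passed, and the median absolute difference was 5.82 against 3.12 percentage points (two-sided permutation test over clusters, p = 0.00013, adjusted 0.00039 over 3 comparisons). The corresponding permutation tests for the allelic difference in F1 and for Adar F1 against F1 gave p = 0.239 and p = 0.350.

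F1 hybrids were set against the mixed parents to ask whether total editing changes when both genomes share a cell. Of 853 sites, 1 differed. This site, 3R 1062097, was edited at 38.3% ± 0.680 (SD, n = 3) in F1 and at 21.4% ± 2.32 (n = 2) in the mixed parents (adjusted p = 0.000139), with all F1 libraries above both mixed libraries. The difference lay on the D. melanogaster allele, which stood at 67.4% ± 3.98 in F1 and 43.8% ± 2.60 in the mixed parents, while the D. sechellia allele stood at 0.890% ± 0.458 and 0.170% ± 0.241. At an unadjusted p under 0.05 there were 61 sites, limma on arcsine-transformed levels also called 1 site, and Fisher's exact test on pooled reads, which leaves out the spread between libraries, called 22. F1 replicate 3 shared the coverage profile of the mixed parents; with it as the only F1 library against both mixed parents, and its spread assumed to be that of the other groups, 3R 1062097 was again the only site called, whereas leaving out F1 replicate 3 gave 2 sites.

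In the F1 hybrids both alleles share the same cells, so the comparison of alleles within a library asks how much of a species difference travels with the allele. Of 512 sites, 151 differed between alleles, 63 with the D. sechellia allele higher and 88 with it lower. In the mixed parents, where the alleles come from separate flies, 135 of 521 sites differed, 56 higher and 79 lower. Among sites under 95% G in both parents, the D. sechellia allele was higher in F1 at X 1267594 (85.4% ± 3.34 against 10.5% ± 4.41, SD, n = 3) and X 3847311 (49.9% ± 7.99 against 6.01% ± 1.28). It was also higher at 2L 16877850 (29.0% ± 4.14 against 1.03% ± 1.14). The D. melanogaster allele was higher at 3R 1062097 (67.4% ± 3.98 against 0.890% ± 0.458), 3L 21327037 (68.4% ± 3.29 against 6.69% ± 0.933) and 2R 4771250 (42.6% ± 4.17 against 3.55% ± 0.649). These 6 sites had adjusted p-values from 2.33e-18 to 7.13e-09. Sites at 95% G or more in a parent gave the largest gaps, such as 3R 5296946 (99.4% ± 0.962 against 0.875% ± 0.243). Without F1 replicate 1 the F1 count was 96, and without mixed parents replicate 1 or 2 the mixed count was 83 or 66.

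Parent and hybrid gaps were then compared over the 472 sites, in 137 clusters, covered in all of these samples; sites are not independent replicates, so intervals come from resampling clusters. Of 193 sites that differed between the species, 175 (90.7%) had an F1 gap of the same sign, and 115 (59.6%) were called in F1 with that sign, where independent lists of these sizes would share 30.4. None of the 193 was called with the opposite sign in F1. Across sites the F1 gap followed the gap between separate parents with r = 0.950 (95% interval 0.914 to 0.969) and rho = 0.730, and the mixed-parent gap did so with r = 0.966 and rho = 0.793. Without the sites at 95% G, r was 0.855 in F1 and 0.905 in the mixed parents. The median gap of the sites that differed between species was 73.6% of the parental gap in F1 (56.7 to 81.2) and 88.8% in the mixed parents (80.04 to 95.95). These sites were chosen by the same separate-parent gap that serves as the divisor, so both percentages tend to be too low. Noise in that gap likewise lowers any slope on it. The slope on the parental gap was 0.912 in F1 and 0.922 in the mixed parents, a difference of -0.010 (-0.0456 to 0.0152). Without the sites at 95% G these slopes were 0.791 and 0.849, a difference of -0.0579 (-0.143 to 0.00955).

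**Figure D2:**
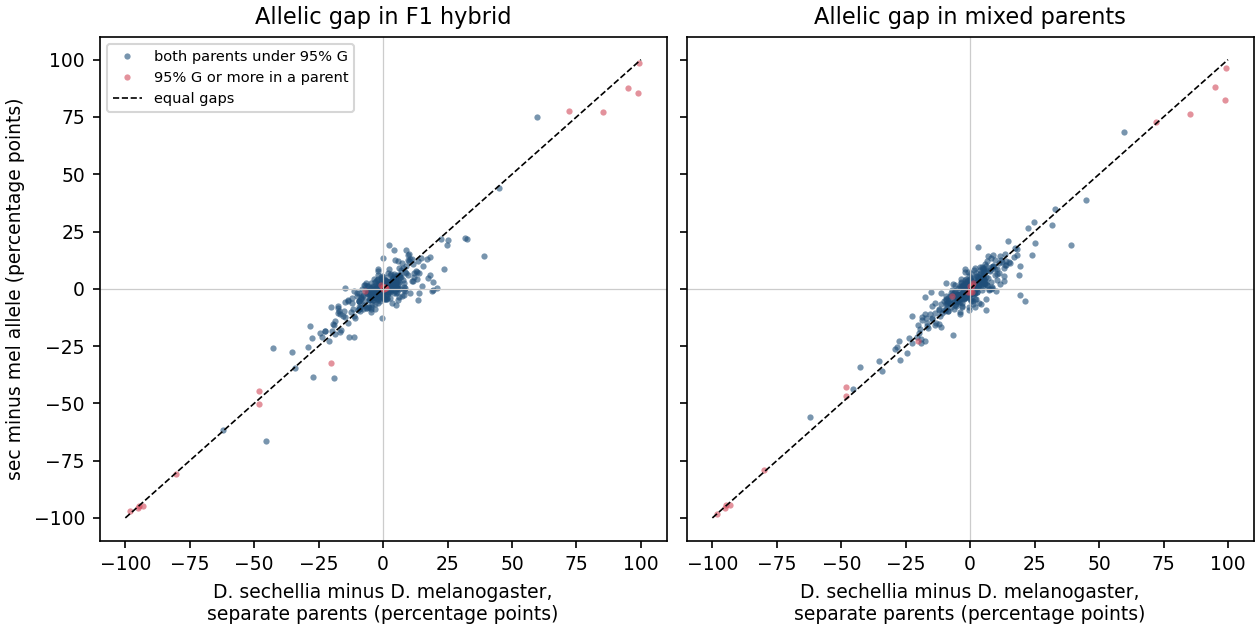
Allelic gap (D. sechellia minus D. melanogaster allele, percentage points) in F1 (left) and in mixed parents (right) against the difference between the separately sequenced parents, for 472 sites, each point a mean over libraries. Red points read as G in 95% or more of a parent's reads, and the dashed line marks equal gaps; the slopes were 0.912 and 0.922.

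A gap that differs between F1 and the separate parents would mark a part of the species difference that does not travel with the allele. Such a difference was called at 28 of 499 sites, the gap moving upward (D. sechellia minus D. melanogaster) at 10 and downward at 18. Of the 28, 5 read at least 95% G in a parent, as did 23 of the 499 tested. For 1 of these, X 4253674, the D. sechellia and D. melanogaster levels were 99.3% and 0.588% in the separate parents and 93.3% and 8.06% in F1. They were 92.9% and 10.6% in the mixed parents, where no hybrid cell is present. At 2L 5363749 the parents differed, at 82.5% ± 1.60 in D. sechellia and 61.4% ± 1.48 in D. melanogaster (SD, n = 2), while the F1 alleles stood at 69.9% ± 3.15 and 69.6% ± 2.54 (n = 3; adjusted p for the change of gap = 0.00723). At 2R 17508581 the gap of 39.1 percentage points between parents was 14.3 points in F1 (adjusted p = 0.000226). At 2R 4771250 the gap widened from -19.0 to -39.1 points (adjusted p = 0.000226), and at X 1267594 from 59.8 to 74.9 points (adjusted p = 0.0207). The count depended on the parental reference: with the mixed parents in place of the separate parents the quasi-binomial test called 0 of 486 sites, with 43 at an unadjusted p under 0.05, and the change of gap at 2L 5363749 turned to 5.44 points. It was 8 with limma, 9 after thinning to equal coverage, and 17, 13 and 14 without F1 replicates 1, 2 and 3.

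The Adar F1 libraries were compared with F1 to ask how editing differed in hybrids carrying the mutant D. melanogaster Adar gene. Of 648 sites, 213 in 108 clusters differed, of which 166 fell and 47 rose. Over all tested sites the median Adar F1 level was 85.2% of the F1 level (80.6 to 89.3, resampling clusters), and 434 sites (67.0%) were lower in Adar F1. By level, no test between groups of sites was run. At sites averaging 5 to 20% the median was 77.1% of F1 (71.4 to 83.6), with 58 of 190 sites falling and 14 rising. It was 79.3% (69.1 to 86.3) at 255 sites under 5%, 88.6% (83.7 to 97.3) at 126 sites from 20 to 50%, 94.8% (91.1 to 102.5) at 55 sites from 50 to 80%, and 99.8% (98.2 to 101.8) at 22 sites above 80%. Levels near the ceiling leave little room for a rise, and 15 of these 22 sites read at least 95% G in a parent; the other 7 stood at a median of 100.6% (89.7 to 101.9).

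Among the falls, editing at X 19228498 went from 54.5% ± 3.34 in F1 to 9.54% ± 1.28 in Adar F1 (SD, n = 3 each; adjusted p = 7.12e-07). The adjacent sites 3L 9826400 and 9826401 went from 50.1% ± 3.93 to 15.5% ± 7.09 and from 68.2% ± 1.77 to 33.9% ± 9.19. The site 2R 3467301 went from 45.4% ± 16.9 to 0.721% ± 0.798. A pair of larger falls lay at sites that read at least 95% G in D. melanogaster: 3L 11218632 (91.4% ± 3.86 to 6.29% ± 3.57), where the D. melanogaster share of reads went from 91.4% to 0.873%, and 2R 6708460 (65.5% ± 4.73 to 0.839% ± 0.381). Among the rises, 2R 11759381 and 11759421 went from 6.37% ± 1.21 to 51.8% ± 2.05 and from 7.77% ± 1.19 to 52.4% ± 0.513 (adjusted p = 1.15e-11 and 1.84e-10). The site 2R 6643569 went from 71.6% ± 5.36 to 98.9% ± 0.783, 2R 8336191 from 37.3% ± 1.11 to 55.0% ± 3.70 and 2L 7230012 from 51.4% ± 2.13 to 67.4% ± 1.23. The largest rise, at 2L 20825935 (1.70% ± 1.07 to 60.4% ± 2.94), went with a D. melanogaster share of reads that moved from 98.2% to 38.5%.

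**Figure D3:**
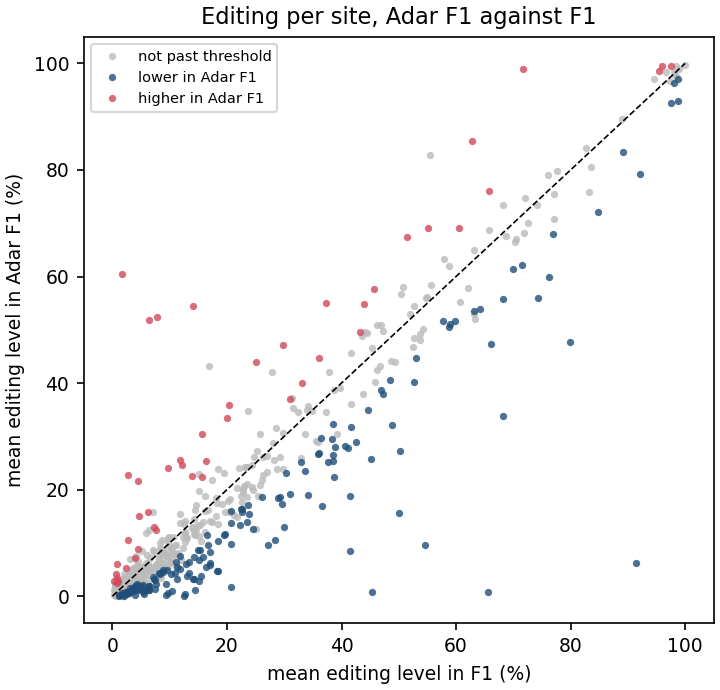
Mean editing level (%) of each of 648 sites in Adar F1 (n = 3) against F1 (n = 3). Blue points are the 166 sites that fell, red points the 47 that rose, grey points sites not past the threshold, and the dashed line marks equal levels.

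Allele shares moved by over 30 percentage points between F1 and Adar F1 at 87 of 747 covered sites, among them 18 of the sites that rose and 16 of those that fell. With such sites left out, 171 of 572 differed, 27 rising and 144 falling. On D. melanogaster allele reads alone, 146 of 515 sites differed (25 rose, 121 fell). On D. sechellia allele reads alone, which had fewer covered sites, 57 of 358 differed (10 rose, 47 fell). The coverage profile over sites correlated by at most 0.528 between an Adar F1 and an F1 library, against 0.899 to 0.978 among F1 libraries and 0.986 to 0.993 among Adar F1 libraries, so coverage batch and Adar genotype cannot be told apart. The labels do not name the D. melanogaster stock that carried the mutation. Other sequence differences of that stock thus cannot be told apart from the Adar genotype either, for rises or for falls.

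**Figure D4:**
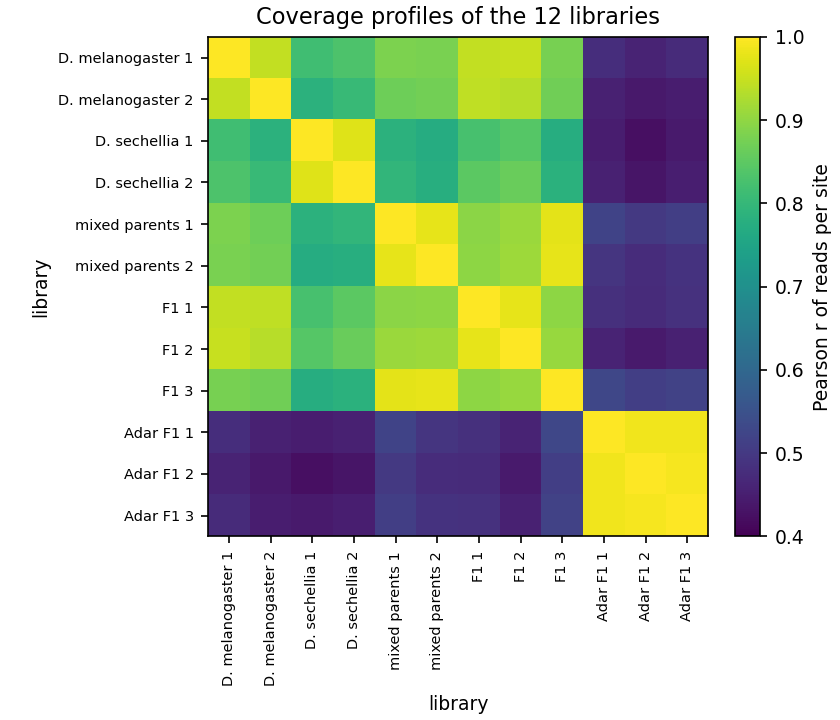
Pearson correlation of reads per site between the 12 libraries (colour scale from 0.4 to 1). The Adar F1 libraries correlate with each other at 0.986 to 0.993 and with F1 libraries at 0.528 or less, and F1 replicate 3 correlates with the mixed parents at 0.974 and 0.978.

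Whether the change in Adar F1 differed between alleles was tested at 324 sites, of which 5 passed, all toward a lower D. sechellia minus D. melanogaster gap. Just short of the threshold, 2R 6708460 and 2L 6002117, chosen after their values were seen, moved the other way by 94.98 and 21.1 points (adjusted p = 0.0549 and 0.0635), the former a site at 95% G in D. melanogaster. At 3L 4590708 the D. melanogaster allele went from 26.9% ± 2.33 to 57.1% ± 1.51 while the D. sechellia allele stood at 33.03% ± 1.08 and 33.2% ± 2.26 (SD, n = 3; adjusted p for the change of gap = 4.29e-05). At 3R 1062051 the D. sechellia allele went from 47.0% ± 7.64 to 16.5% ± 5.32 and the D. melanogaster allele stood at 24.9% ± 2.75 and 21.7% ± 1.34 (adjusted p = 4.29e-05). The others were 2R 11759340, 2L 3762371 and 3R 1062054. At 69 falling sites covered on both alleles, the median change was -7.06 percentage points on the D. melanogaster allele and -7.85 on the D. sechellia allele, with a median difference between alleles of 0.108 (-1.60 to 2.34). At 13 rising sites covered on both alleles, the medians were 10.4 and 6.15, with a median difference of 1.06 (-0.134 to 20.1). The count of 5 was 3 without F1 replicate 1 or 2, without Adar F1 replicate 2 or with thinned reads, 9 without Adar F1 replicate 1, and 13 with limma.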

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

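The tests in this part other than the splits of samples were chosen after the results were seen. Results are listed here where a gap between alleles differed between groups by a test of the difference, or where reads appeared outside the main measurement; the sites that rose in Adar F1 met neither rule and were added after their values were seen.

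Adar F1 libraries rose at 47 sites where an Adar mutation would be taken to lower editing. A shift in the mix of allele reads is argued against as the whole cause, since at the 42 risers with a within-allele value the median within-allele change was 84.1% of the median total change (51.7 to 101.3). Allele shares did move by over 30 percentage points at 18 of the 47 risers, among them 2L 20825935. At the 21 risers with the D. sechellia allele covered, that allele changed by a median of 6.15 percentage points (2.34 to 11.1), and 10 rises were called on it. These sites were chosen for a rise in totals that include D. sechellia reads. The median therefore cannot decide whether a sequence difference acted on the D. melanogaster allele alone. That explanation is argued against only at sites among the 10 called on D. sechellia reads, provided that reads were assigned to the right allele. Of these 10, 5 lay on 3R from 23500441 to 23500650. At 23500441, 23500444, 23500458 and 23500461 the D. melanogaster allele had at least 116 reads per library in F1 and as few as 0 in Adar F1. The least D. sechellia reads there went from 65 to 353. Moved D. melanogaster reads could give such a rise, so these sites cannot decide. The explanation stays open there and at the risers not called on D. sechellia reads, among them 26 without the D. sechellia allele covered. At 3L 4590708 the change was 30.2 points on the D. melanogaster and 0.212 on the D. sechellia allele. At 10 sites called to rise on D. melanogaster reads alone the D. sechellia allele changed by a median of 0.950 (-0.833 to 17.7). Different amplification of the Adar F1 libraries also stays open, because the highest coverage correlation with an F1 library was 0.528, and a biological effect of the mutation is confounded with it.

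The gap differed between F1 and the separate parents at 28 sites, among them 2L 3762337 (16.5 percentage points, F1 minus parents), X 2275082 (15.2), X 1267594 (15.0), 2R 17508581 (-24.7), 2L 5363749 (-20.8) and 2R 4771250 (-20.1). Of the 28 sites, 5 read at least 95% G in a parent. Counting of alleles in a sample of both species stays open because its tests disagree: the slope on the parental gap differed between F1 and mixed parents by -0.010 (-0.0456 to 0.0152), while the median gap as a percent of the parental gap differed by -15.2 (-26.6 to -7.13). Both intervals resample clusters and leave out the spread between libraries. By library, the median percent was 71.0, 67.2 and 74.2 in F1 replicates 1, 2 and 3, and 85.3 and 93.3 in mixed parents replicates 1 and 2. At sites called without an F1 library, the gap in that library had moved further than in the mixed parents by a median of 3.59 (-1.06 to 6.41), 4.53 (1.11 to 8.23) and 1.14 (-2.51 to 3.81) percentage points for replicates 1, 2 and 3. Replicate 3, with the smallest value, shared the coverage profile of the mixed parents (r = 0.974 and 0.978). Coverage batch was therefore not separated from these values. An effect of the hybrid cell stays open too, as at the 27 called sites covered in the mixed parents these showed a median of 50.9% of the change (33.96 to 63.7). That value is raised by the separate parents shared by both differences and lowered by choosing sites for their F1 change, so neither explanation is excluded, and 0 sites passed the quasi-binomial test against the mixed parents (43 at an unadjusted p under 0.05). At 3R 1062097, whose total editing differed between F1 and mixed parents, the gap was -66.5 points in F1. It was -43.6 in the mixed and -45.4 in the separate parents. With its D. sechellia allele under 1%, this change of gap from the separate parents did not pass on the log-odds scale (quasi-binomial test, adjusted p = 0.847).

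Reads assigned to the other species made up 2.10% and 2.08% of the D. melanogaster libraries and 3.76% and 1.29% of the D. sechellia libraries, whose own-species measurement leaves them out. For the excess in D. sechellia replicate 1, wrong assignment in a fixed share at each site is argued against: at 964 sites, the site shares of replicate 2 at the coverage of replicate 1 gave 38.7% (17.03 to 62.96) of its other-species reads, while the same calculation for D. melanogaster gave 99.6% (91.3 to 107.8). D. melanogaster RNA spread over the whole library is argued against too, because 55.3% of 978 covered sites had below 0.1 times the library's share. At 71 sites in 17 clusters with 5% or more in replicate 1 and under 5% in replicate 2 lay 4788 of its 11647 other-species reads. Carry-over of D. melanogaster amplicons stays open, as the G percent of these reads at 27 of the sites lay a mean of 9.47 points from D. melanogaster and 8.11 from D. sechellia replicate 2, a difference of 1.36 (-1.53 to 3.33); an assignment error that differs between libraries and variation within the stock were not tested, and no biological explanation was tested.

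The change in Adar F1 differed between alleles at 5 sites, including 3L 4590708 (-29.99 percentage points, Adar F1 gap minus F1 gap), 3R 1062051 (-27.3) and 2R 11759340 (-23.2). Too few splits exist for a share under 0.05 in the following tests. Of the 10 splits of the 6 F1 and Adar F1 libraries, 1, the real one, gave 213 differing sites, and the highest other split gave 0; for the change of gap the real split, again 1 of 10, gave 5 and the highest other 0. Of 4 assignments of alleles in the 3 F1 libraries, 1, the real one, gave 151 sites and the highest other 2.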

How the results depend on the processing

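Alternatives said in the methods to be added after seeing the data are so here too. Of 1562 alternative values at 106 named site results, 1436 kept their direction and side of the threshold, 123 lost the threshold and 3 turned around. With mixed parents as the species difference, the change of gap became 5.44 percentage points at 2L 5363749, 2.42 at 3L 4369162 and 2.99 at X 4253674; the cause was not tested. The species count stayed within 1.5 times under each alternative, from 222 at a minimum level of 5%, which tests fewer sites, to 386 with Fisher's exact test, and from 253 to 268 leaving out a replicate. Adar F1 against F1 gave 157 to 242 leaving out a replicate and 57 with D. sechellia allele reads alone, which covered fewer sites. F1 against mixed parents, with 1 site, gave 22 with Fisher's exact test, 2 with only the compared groups, 2 with D. melanogaster allele reads alone, 0 with D. sechellia allele reads alone (13 at an unadjusted p under 0.05), and 1 to 2 leaving out a replicate. Alleles in F1 gave 96 to 120 leaving out a replicate. Alleles in mixed parents gave 87 at 100 reads, which leaves fewer sites, 81 with no level filter and 66 to 83 leaving out a replicate. The change of gap in F1, with 28 sites, gave 8 with limma, 9 with thinned reads, 0 with mixed parents (43 at an unadjusted p under 0.05) and 13 to 32 leaving out a replicate. The change of gap in Adar F1, with 5 sites, gave 3 with no level filter, 13 with limma, 3 with thinned reads and 3 to 9 leaving out a replicate. Apart from smaller sets of sites or libraries, causes were not tested. Where a left-out replicate leaves 1 library in a group, that library is assumed to vary like the other groups. The differences in mean editing per library between species, F1 and mixed parents, and Adar F1 and F1 moved by less than the larger SD of the groups compared under every alternative tried (the species difference, at -2.48, was -1.76 with pooled reads); the other pairs were not recomputed.

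Replicate numbers were not used to pair the samples in the main tests. Deviations of F1 and Adar F1 libraries of the same number correlated by 0.146, 0.138 and 0.0435. Of these 6 libraries, 5 correlated best with their own number, so a pairing by number cannot be excluded. With the replicate block the counts were 311 for the species, 1 for F1 against mixed parents, 205 for Adar F1 and 33 for the change of gap in F1. Alternatives for gene lists were not run, for want of gene names. Thinned reads lowered the gap counts to 9 and 3, and the self-test recovered 8.82% of simulated gap changes of 0.5 in log odds.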

Other observations

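The regions described first were chosen after their values were seen, by their number of called sites; the neighbour tests were fixed before their result was seen, except those that leave out a cluster or the sites at 95% G. On 3R from 1061931 to 1062100, 11 sites were covered, of which 2 were higher and 7 lower in D. sechellia. In F1, the 2 sites 1062051 and 1062054 were higher on the D. sechellia allele, and 8 sites were higher on the D. melanogaster allele. At 1062100 the D. melanogaster allele was edited at 27.8% ± 1.43 (SD, n = 2) in the parent, 31.6% ± 1.69 (n = 2) in the mixed parents and 39.6% ± 6.33 (n = 3) in F1, and the D. sechellia allele stayed under 1% in each. At 1062054 the D. melanogaster allele was at 76.8% ± 0.531 in the parent, 75.5% ± 0.940 in the mixed parents and 90.2% ± 2.52 in F1.

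On 2R from 13262372 to 13262655, 22 of 24 sites were tested in Adar F1, and 16 fell while 2 rose. The D. sechellia allele had few reads here, at most 25 per site and library in F1, and at part of the sites as few as 1 in Adar F1. On D. melanogaster allele reads alone, 16 of 21 sites fell and 0 rose, so neither rise was called within that allele. On this allele the site 13262562 went from 45.7% ± 1.95 to 25.9% ± 1.26 (SD, n = 3 each). The adjacent site 13262563, at 95% G or more in D. sechellia, went from 34.03% ± 1.02 to 16.9% ± 1.78. The same allele at these sites averaged 30.7% and 18.8% in D. melanogaster, and 42.2% and 27.9% in the mixed parents (n = 2 each). Its level thus also differed between libraries without the Adar mutation, so these falls cannot be put down to the mutation alone. At 13262537 this allele averaged 6.72% in D. melanogaster, 14.5% in the mixed parents, 14.0% in F1 and 0.0694% in Adar F1. Its coverage changed as well, from at least 130 reads per library in F1 to at least 480 in Adar F1. The nearby sites 13262533 and 13262534 had as few as 0 reads in Adar F1. The fall at 13262537 thus cannot be told apart from a change in the amplified fragment. On 3R from 23500441 to 23500650, 5 of 12 tested sites rose and none fell. On D. sechellia allele reads alone 5 of 12 sites rose, of which 1 had the D. melanogaster reads in Adar F1 to be tested on that allele. On D. melanogaster allele reads alone, 0 of 8 tested sites rose. At 23500458 the D. sechellia allele was at 60.2% ± 2.61 in F1 and 85.4% ± 2.58 in Adar F1, where the D. melanogaster allele had too few reads; at 23500600, with both alleles covered, the D. melanogaster allele was at 61.3% ± 2.74 and 68.5% ± 2.66 and the D. sechellia allele at 59.8% ± 4.21 and 69.9% ± 4.01.

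A total of 183 sites had no read in any Adar F1 library, and 148 of these had at least 50 reads in every F1 library. At 32 sites that held both alleles in F1, the D. melanogaster allele took under 5% or over 95% of the reads in Adar F1.

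The hypothesis that allele differences act on groups of neighbouring sites was tested on the direction of the F1 gap. Of 158 pairs of called sites within 100 bases, 72.2% shared a direction, against 51.1% (44.3 to 60.1) when directions were permuted (one-sided permutation p = 5e-05), and 75.6% of 123 pairs did so without the cluster that holds most pairs. Without sites at 95% G the share was 74.8% of 135 pairs. Of 38 pairs between 100 and 1000 bases apart, 47.4% did so (permutation p = 0.729). A candidate explanation is therefore a local one, but neighbouring sites may also share directions because they are read from the same sequenced molecules, and the value of the distant pairs, below the permuted range's upper bound of 68.4%, is in line with that too.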
